A study of Arabidopsis thaliana with 16 samples.

How the data were processed

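RNA was measured in 16 libraries of Col-0 Arabidopsis seedlings grown in vitro for 15 days. In the zeocin experiment, 5 libraries came from seedlings exposed to zeocin (200 microg/ml for 3 h) and 5 from mock seedlings. In the UV-C experiment, 3 libraries came from seedlings exposed to UV-C (8 kJ/m2) and 3 from their own mock seedlings. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRI reagent, depleted of ribosomal RNA and made into strand-marking libraries with the NEBNext Ultra Directional kit. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

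The values used are raw counts of fragments per assembled locus, deposited by the authors as 1 table per experiment. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.11.8 and aligned with STAR 2.7.1a, and the genome build was TAIR10. Per the file headers, transcripts were assembled with StringTie 2.1.5 in strand mode from a merged alignment of each experiment without a reference annotation, and counts were made with featureCounts 2.0.1 over exons with the strand used. Fragments that map to several places or to several loci were not counted under those options, so members of near-identical gene families are undercounted. The assemblies differed in their options, per the file headers. Both required transcripts of at least 200 bases. The zeocin assembly asked for a coverage of at least 10 and the UV-C assembly for at least 1, or 2 for transcripts with a single exon. Only the UV-C assembly raised the share that a transcript must reach of the most abundant one at its place to 0.5. Opposite-strand loci overlapped 23 of the 257 unannotated antisense loci of the zeocin table and 5 of the 348 in the UV-C table. Most antisense loci thus had no counts of the opposite strand at the same place. In the UV-C table measured sense genes were mostly counted over another part of their length, and for zeocin this was not determined. Locus numbers were given separately in each assembly, and the same number names different loci.

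There were 20880 loci in the zeocin table and 22818 in that of UV-C. Each nuclear locus was compared with the TAIR10 chromosomes and annotation of the reference given for this work. Of the introns of the zeocin loci 97.6% matched an annotated intron exactly, and of those of the UV-C loci 99.2%. A locus was given a gene on its strand when their exonic overlap was at least 50% of the exonic length of either the gene or the locus. A gene's value can therefore rest on a locus that covers only part of it. Genes under 200 bases were ignored where a longer one was held, and a locus with several remaining genes was kept as a class of its own and named for no gene. Where several loci held 1 gene, that with the longest overlap stood for it. Loci with no gene on their strand were called unannotated antisense when they overlapped a gene on the other strand and unannotated intergenic otherwise. Mitochondrial loci were not annotated, because the sequence used in the files could not be matched to the reference. Chromosome coordinates are 1-based TAIR10 positions of the assembled locus. All columns of per-sample values were mapped to samples.

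Changes were tested with edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with the quasi-likelihood test, TMM factors, edgeR's default filter on low counts and robust dispersions. Each experiment was fitted alone, treated against mock, two-sided, and a locus was called at a Benjamini-Hochberg adjusted p below 0.05. The filter left 19447 zeocin loci and 19587 UV-C loci. The difference between the responses was the interaction term of a joint fit over loci that held the same gene in both tables, or unannotated loci that overlapped reciprocally by at least 50%. That fit tested 17305 loci. The tables were counted on different assemblies, so levels were compared only within a table. Fold changes are log2 values with standard errors derived from the test statistic, and levels are TMM-scaled CPM, edgeR's counts relative to library size. A group with 0 counts was set to 3 counts over the group, and the fold was then given as a lower bound. With 1 to 3 counts the ratio of pooled counts was given with its exact 95% interval. Intervals and floors cover counting error only.

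Before the data were examined, 20 gene lists were fixed together with the tests, the alternatives and the rule for naming loci. The lists were the SOG1-dependent damage response, homologous recombination, end joining, nucleotide excision repair with photolyases and translesion synthesis, base excision repair, checkpoint and cell cycle arrest, G2 and mitosis, DNA replication and S phase, flavonoids and UV protection, heat shock and protein folding, oxidative stress and detoxification, salicylic acid and defence, jasmonate with ethylene and wounding, abscisic acid and senescence, photosynthesis, root tissue, meristem and stem cell niche, stomatal lineage, circadian clock, and known long non-coding RNAs. Each was tested against the other loci with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. A list's p was adjusted over the lists of its comparison. The rule named, per treatment, the 5 rising and 5 falling single-gene loci with the largest fold changes among those called, at a mean log2 CPM of at least 1 and with no overlap between treated and mock CPM. It added 4 rising and 2 falling unannotated loci at a mean log2 CPM of at least 0, the 2 members of each list with the smallest p, and SOG1, BRCA1, SMR5, SMR7, CYCB1;1, NAC044, PHR1 and CHS whatever their values. A further item that the rule names is not reported here. For the difference it named 4 genes and 3 unannotated loci in each direction.

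Rising shares of locus classes were compared with that of protein-coding loci by Fisher's exact test, two-sided, and overlaps of calls likewise. These tests count loci, which are not independent replicates, and their p-values measure no spread between samples. Fold changes of antisense loci and their sense genes were correlated across loci with 100000 permutations, or exactly below 10 pairs. Library shares were compared by exact permutation of the samples.

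The procedure was tested on simulated counts with the means, dispersions and library sizes of each experiment, in 5 draws with 200 changed loci each. In the zeocin design 26.4% of loci with a true log2 change of 0.5 were recovered, 72.0% at 1, 90.8% at 2 and 93.6% at 3, and 5.73% of calls were of unchanged loci. In the UV-C design the shares recovered were 32.8%, 75.2%, 92.0% and 94.0% at the same sizes, and 13.0% of calls were of unchanged loci (10.5% to 15.7% over the draws). The UV-C share lies above the level that the threshold sets. The simulations changed far fewer loci than were called in the data. Neither recovery nor the share of unchanged loci among calls was measured at the real number of changes. For the interaction the shares recovered were 6.40%, 57.2%, 85.2% and 92.0%, with 4.90% of calls unchanged.

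Alternatives were DESeq2 1.42.0, RLE and upper quartile factors, no filter on low counts, a filter of at least 10 counts in every library of a group, removal of organellar and rRNA loci, a threshold of 1 on the absolute log2 fold change, the replicate number as a block, 80% reciprocal overlap for matching, fry in place of camera, and leaving out each library. Added after the data were seen were fits without replicate 1 of both zeocin groups and another choice of locus for sense genes held by several loci. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 served for annotation, further tests and plots.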

Results

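RNA was sequenced from Arabidopsis seedlings after exposure to zeocin, a bleomycin-type drug that breaks both DNA strands, or to UV-C, which forms pyrimidine dimers. The series was designed to find long non-coding RNAs with a part in the repair of double-strand breaks, by setting these treatments side by side on transcripts assembled from the reads. There were 5 mock and 5 zeocin libraries and, in a separate experiment, 3 mock and 3 UV-C libraries. Total counts per library ranged from 31329853 to 41488445 in the zeocin mock group, from 31185080 to 44536500 after zeocin, from 32161555 to 37507136 in the UV-C mock group and from 27973871 to 30014943 after UV-C.

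The zeocin comparison asked which transcripts differed after 3 h of the drug. Among the loci that rose were genes of the DNA damage response. BRCA1 (AT4G21070, chromosome 4, 11248078 to 11252823), a partner in homologous recombination, rose from 4.28 ± 0.279 to 576 ± 40.3 CPM (SD, n = 5). SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, rose from 0.360 ± 0.193 to 190 ± 30.0 CPM, and the B-type cyclin CYCB1;1 (AT4G37490) from 3.77 ± 0.445 to 140 ± 4.96 CPM. Most measured genes of the mitotic and root lists fell. By edgeR's quasi-likelihood test 2917 of 19447 loci rose and 2328 fell at an adjusted p below 0.05, and 1004 and 406 of them changed by at least 1 on the log2 scale. The balance of directions depended on the scaling of the libraries: 55.6% of calls were rises with TMM factors and 44.9% with upper quartile factors.

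Of the 18 measured members of the list of genes known to depend on SOG1, the transcription factor that directs the plant damage response, 17 rose after zeocin and 1 fell (median log2 fold change 5.10, camera adjusted p = 4.18e-206). The same counts held when p was adjusted over the list alone. XRI1 (AT5G48720), required for repair after X-rays, rose by 6.30 ± 0.11 (log2, SE, adjusted p = 1.31e-14), and NAC085, a NAC factor of the same pathway, by 7.91 ± 0.35. The member that fell was BARD1, with a log2 fold change of -1.13 ± 0.19. SOG1 itself, which is controlled by phosphorylation, did not pass the test (log2 fold change 0.14 ± 0.11, adjusted p = 0.383). SMR5, NAC044 and PARP2 were not held alone by a locus in the zeocin assembly and have no value.

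Homologous recombination genes rose in 11 of 24 measured cases and fell in 3 after zeocin, or in 13 and 3 adjusted over the list alone (median 0.38, camera adjusted p = 1.33e-44). Of the 11 that rose 6 are also on the SOG1-dependent list. Besides BRCA1 the rises included COM1 (5.68 ± 0.16), which starts the resection of DNA ends, and RPA1E (4.64 ± 0.12), which binds single strands, whereas BRCA2A (-0.88 ± 0.16) and MRE11 (-0.65 ± 0.12) fell. End joining genes rose in 2 of 9 cases, PARP1 by 3.97 ± 0.10 and the ligase LIG4 by 0.94 ± 0.09, of which PARP1 is also SOG1-dependent, while KU70 had 0.08 ± 0.10 and KU80 -0.01 ± 0.09 (camera adjusted p = 0.00147, and adjusted p = 0.0637 with an estimated correlation). Checkpoint genes rose in 6 of 12 cases and fell in none, or in 8 adjusted over the list alone (median 1.33, camera adjusted p = 2.04e-25). All 6 are also on the SOG1-dependent list, and none of the 6 other measured checkpoint genes was called over all loci (lowest adjusted p = 0.0851). The calls over all loci therefore rest on genes of that list. The further rises adjusted over the checkpoint list alone are of genes outside it, which were not tested as a set. RAD17, a clamp loader of the checkpoint, rose by 3.76 ± 0.10. The kinases ATM and ATR did not pass the test, with -0.09 ± 0.11 and 0.36 ± 0.15. The calls of the SOG1-dependent, recombination and checkpoint lists held with an estimated correlation (adjusted p = 3.82e-06, 0.000208 and 0.000246).

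Excision repair and photolyase genes rose in 3 of 17 cases and fell in none (camera adjusted p = 0.238). CHR8, which acts in transcription-coupled repair, rose by 2.02 ± 0.13. XPB2, a helicase of transcription factor IIH, rose by 0.32 ± 0.10 with an adjusted p of 0.0300, which became 0.0581 with upper quartile factors and 0.0554 to 0.0878 without any of zeocin mock replicates 1, 2 and 5 or zeocin replicates 2 and 4. The photolyase gene PHR1 (AT1G12370) did not change detectably (-0.09 ± 0.26, adjusted p = 0.843). Base excision repair genes rose in 4 of 9 cases and fell in 1 (camera adjusted p = 0.238), among them APE1L at 1.53 ± 0.12 and ARP at 0.40 ± 0.11.

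Genes of G2 and mitosis fell in 17 of 23 cases after zeocin and rose in none, or fell in 21 adjusted over the list alone (median log2 fold change -0.92, camera adjusted p = 4.82e-09, and adjusted p = 0.0637 with an estimated correlation). CYCB1;3 had a log2 fold change of -1.45 ± 0.17 and the cytokinesis syntaxin KNOLLE of -0.99 ± 0.12. CYCB1;1, listed with the damage genes, went the other way. Replication and S phase genes fell in 15 of 18 cases and rose in 2, or fell in 16 adjusted over the list alone. The 2 that rose were the ribonucleotide reductase genes RNR1 (3.13 ± 0.09) and TSO2 (6.22 ± 0.12), which make deoxynucleotides. With these the mean was -0.18 and the median -0.70, and the list did not pass camera (adjusted p = 0.202). Root tissue genes fell in 9 of 13 cases, or fell in 11 and rose in 1 adjusted over the list alone (median -0.89, camera adjusted p = 1.00e-06, and adjusted p = 0.0637 with an estimated correlation). They included the nitrate transporter NRT2.1 (-2.81 ± 0.19), the phosphate transporter PHT1;1 (-1.44 ± 0.10) and CASP1 (-1.20 ± 0.11) of the Casparian strip.

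Oxidative stress and detoxification genes rose in 9 of 16 cases after zeocin and fell in none (median 1.48, camera adjusted p = 1.15e-05, and adjusted p = 0.390 with an estimated correlation). The glutathione transferases GSTU25 and GSTU24 rose by 4.78 ± 0.26 and 1.81 ± 0.23. Jasmonate, ethylene and wounding genes rose in 7 of 16 cases, or 9 adjusted over the list alone (median 0.55, camera adjusted p = 0.00147, and adjusted p = 0.199 with an estimated correlation), with the biosynthetic gene AOC1 at 2.34 ± 0.12 and the repressor JAZ5 rising 2.47-fold. Salicylic acid and defence genes rose in 6 of 17 cases (camera adjusted p = 0.0802), among them EDS1 at 1.22 ± 0.13 and NPR1 at 0.48 ± 0.08. Of 14 abscisic acid and senescence genes 2 rose and 1 fell (camera adjusted p = 0.462). NYE1, which starts chlorophyll breakdown, rose by 1.29 ± 0.14 and the phosphatase gene HAI1 by 1.32 ± 0.31.

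Other lists passed no camera test after zeocin. Flavonoid and UV protection genes rose in 1 of 20 cases and fell in 3, or rose in none and fell in 3 adjusted over the list alone (camera adjusted p = 0.244), with FLS1 at -1.15 ± 0.21, UGT78D1 at -0.87 ± 0.20 and CHS, chalcone synthase, not passing at -0.25 ± 0.12. Heat shock genes rose in 2 of 15 cases, or 1 adjusted over the list alone (camera adjusted p = 0.525): HSFB2A by 1.47 ± 0.12 and HSFB1 by 0.42 ± 0.14. The adjusted p of HSFB1 was 0.0438, became 0.0675 with upper quartile factors and lay between 0.0648 and 0.103 without any of zeocin mock replicates 1 to 4 or zeocin replicates 2, 3 and 5. None of 18 photosynthesis genes was called (median -0.19, camera adjusted p = 0.186). PSBO1 had -0.26 ± 0.11 and LHCB1.3 -0.25 ± 0.13; without zeocin replicate 1 both passed, at adjusted p of 0.0316 and 0.0371, and PSBO1 also without zeocin mock replicate 5 (0.0474). Meristem genes fell in 3 of 7 cases, with 1 rising adjusted over the list alone (camera adjusted p = 0.193). SCR and SHR, which pattern the root, had -0.56 ± 0.09 and -0.58 ± 0.12. Of 7 stomatal lineage genes SPCH fell (-0.70 ± 0.19) and EPF1 did not pass at -0.94 ± 0.37 (camera adjusted p = 0.244). Of 14 clock genes LHY rose by 1.02 ± 0.12, while GRP7 (-0.53 ± 0.10) and GI (-0.36 ± 0.08) fell (camera adjusted p = 0.723). The clock list's mean was 0.02, opposite in sign to its median of -0.07 and its test.

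The number of lists called is not firm evidence by itself. At the preset correlation 8 lists were called after zeocin, and other splits of the same 10 libraries gave up to 13.

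Within the naming rule's limits on level and overlap, the single-gene loci with the largest rises after zeocin were AT1G20750, a RAD3-like helicase gene (chromosome 1, 7203359 to 7208918), at 10.63 ± 0.38, AT5G07165 at 10.09 ± 0.33, the F-box gene AT5G07610 at 10.04 ± 0.26, SMR7 at 9.07 ± 0.24 and the non-coding AT4G09215 (chromosome 4, 16891311 to 16891818, 1 exon) at 8.82 ± 0.29, the last from 0.533 ± 0.269 to 241 ± 38.7 CPM. Within the same limits the largest falls were NRT2.1, the nitrate transporter NRT1.5 (-2.80 ± 0.12), AT2G48080 (-2.65 ± 0.19), AT2G28780 (-2.44 ± 0.16) and the xyloglucan enzyme gene XTH33 (-2.18 ± 0.20). None of the 7 measured known long non-coding RNAs was called after zeocin (camera adjusted p = 0.624). TAS1A had -0.17 ± 0.12. TAS3, a precursor of small interfering RNAs, had -0.61 ± 0.24 at an adjusted p of 0.0771, which became 0.0435 without zeocin mock replicate 4 and 0.0314 without zeocin replicate 1.

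**Figure D1:**
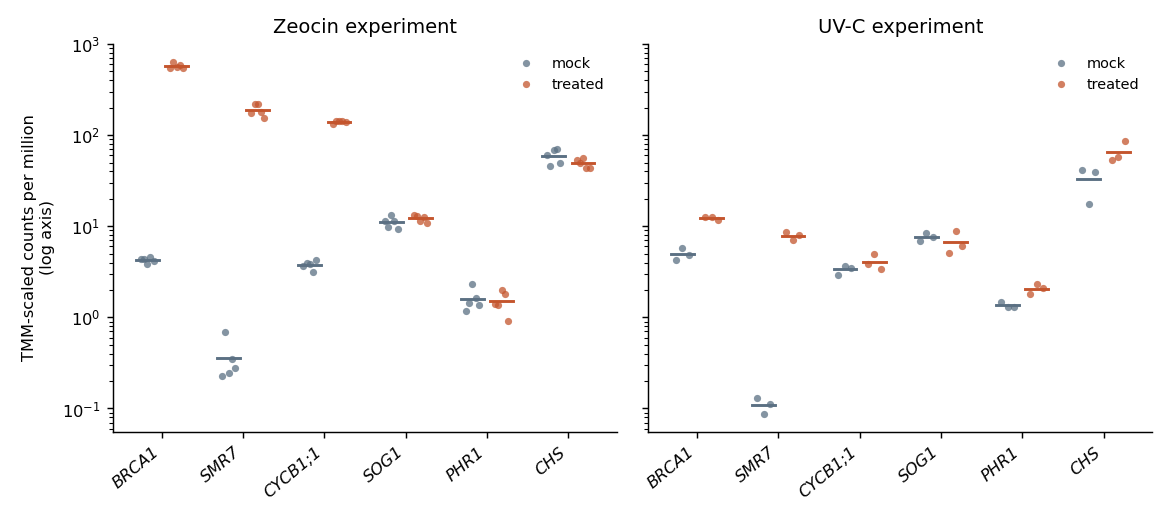
TMM-scaled CPM (log axis) of 6 genes in each library of the zeocin experiment (left, 5 mock and 5 treated) and the UV-C experiment (right, 3 and 3); points are libraries and bars group means. BRCA1 rose from a mean of 4.28 to 576 CPM after zeocin and from 4.98 to 12.4 CPM after UV-C.

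The UV-C comparison asked the same of 8 kJ/m2 of UV-C. The time between exposure and harvest is not given in the sources used here. Most measured genes of the stress and hormone lists rose, by the smallest margin those of abscisic acid (8 of 15). ACS2 (AT1G01480), an enzyme of ethylene synthesis, rose from 0.174 ± 0.0267 to 71.1 ± 1.97 CPM (SD, n = 3), the transporter gene ABCG40 (AT1G15520) from 0.392 ± 0.0759 to 615 ± 70.6 CPM and the alternative oxidase gene AOX1A rose by 3.40 ± 0.09 on the log2 scale (SE). Most measured genes of the mitotic list and all 7 of the stomatal list fell, and the clock genes split into rising and falling members. Of 19587 loci 6572 rose and 6051 fell by edgeR's quasi-likelihood test, and 3557 and 1984 of them changed by at least 1 on the log2 scale. The balance of directions again depended on scaling: 52.1% of calls were rises with TMM factors and 44.8% (5758 up and 7099 down) with upper quartile factors, which moved the median log2 fold change by -0.11.

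The make-up of the libraries moved with UV-C. Plastid transcripts took 45.3% ± 1.33 of counts in mock and 38.6% ± 1.81 in treated libraries (SD, n = 3), residual rRNA 0.00694% ± 0.000972 and 0.0882% ± 0.0129, small structured RNAs 0.496% ± 0.0617 and 0.975% ± 0.109, unannotated loci 0.417% ± 0.0401 and 1.17% ± 0.131, and loci that hold several genes 3.68% ± 0.0610 and 8.83% ± 1.03, in which the single locus STRG.1401 took 1.57% ± 0.0941 and 5.60% ± 0.826. The 10 most abundant loci took 47.8% and 51.4% on average, and total counts were 33970000 ± 3070000 and 29030000 ± 1020000. For each the exact permutation p was 0.1 (two-sided), the smallest that 3 against 3 allow, and 0.129 after adjustment over 9 measures. In the zeocin experiment the unannotated share was 0.101% ± 0.0135 in mock and 0.119% ± 0.00923 in treated libraries (n = 5, exact permutation p = 0.0476, adjusted p = 0.286).

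Damage response genes rose after UV-C by less than after zeocin in most members. SOG1-dependent genes rose in 16 of 20 cases and fell in none (median 0.99, camera adjusted p = 0.00172, and adjusted p = 0.613 with an estimated correlation). SMR5 rose by 8.51 ± 0.20 and SMR7 by 6.12 ± 0.22, BRCA1 by 1.31 ± 0.12 and NAC044 by 3.46 ± 0.41. CYCB1;1 did not pass (0.29 ± 0.18, adjusted p = 0.177), nor did SOG1 (-0.18 ± 0.19, adjusted p = 0.428), which passed at 0.0264 without UV-C replicate 2. Checkpoint genes rose in 7 of 13 cases and fell in 1, ATM (-0.75 ± 0.10; median 0.49, camera adjusted p = 0.0368, and adjusted p = 0.445 with an estimated correlation), and 6 of the 7 that rose are also on the SOG1-dependent list. Recombination genes rose in 6 and fell in 7 of 24 cases (camera adjusted p = 0.717), including FAN1 at -1.20 ± 0.12. The median of -0.19 and the mean of 0.00 lay on different sides of 0. End joining genes rose in 2 and fell in 2 of 10 cases (camera adjusted p = 0.842), PARP2 at 1.40 ± 0.16 against XRCC1 at -1.20 ± 0.14, with a median above 0 and a test direction below. Excision repair, photolyase and translesion genes rose in 3 and fell in 6 of 15 cases (camera adjusted p = 0.560). PHR1, which reverses pyrimidine dimers in light, rose by 0.61 ± 0.19 (adjusted p = 0.0176), with adjusted p of 0.0555 without UV-C mock replicate 3 and 0.0760 without UV-C replicate 2, while XPB1 (-0.69 ± 0.08) and RAD4 (-0.50 ± 0.09) fell. Base excision repair genes fell in 3 of 8 cases and rose in none (camera adjusted p = 0.560), among them ROS1 at -0.54 ± 0.10.

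Genes of G2 and mitosis fell in 22 of 24 cases after UV-C (median -1.81, camera adjusted p = 1.65e-06, and adjusted p = 0.698 with an estimated correlation), with the kinesin HIK at -1.96 ± 0.13 and the spindle factor TPX2 at -1.92 ± 0.16. Replication and S phase genes fell in 7 of 19 cases and rose in 1 (camera adjusted p = 0.279), with the histone H3 genes HTR3 at -1.06 ± 0.11 and HTR9 at -0.72 ± 0.12. All 7 measured stomatal lineage genes fell (median -1.50, camera adjusted p = 0.0670), FAMA by 1.31 on the log2 scale and MYB60 with -1.46 ± 0.19. Root genes fell in 2 of 14 cases, NRT2.1 (-0.97 ± 0.26) and PHT1;1 (-1.20 ± 0.29), and rose in 1, or in none adjusted over the list alone (camera adjusted p = 0.597). Photosynthesis genes fell in 12 of 19 cases and rose in 5 (median -0.24, camera adjusted p = 0.189), with PSAF at -1.10 ± 0.08 and RBCS1A at -0.77 ± 0.07. Meristem genes rose in 2 of 5 cases (camera adjusted p = 0.895). ERF114 rose by 3.54 ± 0.66, and KNAT1 by 0.77 ± 0.27 at an adjusted p of 0.0304, which became 0.0553 with upper quartile factors and 0.0593 to 0.0890 without any of UV-C mock replicates 1 and 3 or UV-C replicates 1 and 2.

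Oxidative stress genes rose in 15 of 16 cases after UV-C (median 4.19, camera adjusted p = 8.41e-21, and adjusted p = 0.141 with an estimated correlation), with the mitochondrial stress gene UPOX at 5.55 ± 0.12. Salicylic acid and defence genes rose in 13 of 15 cases (median 2.82, camera adjusted p = 5.20e-12, and adjusted p = 0.141 with an estimated correlation), with the immune regulators SARD1 at 4.35 ± 0.13 and CBP60G at 2.82 ± 0.11. Jasmonate, ethylene and wounding genes rose in 15 of 16 cases (median 3.46, camera adjusted p = 2.44e-15, and adjusted p = 0.165 with an estimated correlation), LOX3 by 3.87 ± 0.10 and ACS2 by 8.64 ± 0.12, while LOX2 fell (-2.37 ± 0.37). Heat shock genes rose in 15 of 16 cases (median 3.74, camera adjusted p = 0.000831, and adjusted p = 0.698 with an estimated correlation), with FES1A at 1.91 ± 0.09 and HSFB2A at 2.37 ± 0.15. For 2 heat shock genes every mock library had 0 counts, and the median was the same with these at their bound. Flavonoid and UV protection genes rose in 13 of 19 cases and fell in 1 (median 1.18, camera adjusted p = 0.00502, and adjusted p = 0.721 with an estimated correlation), with PAL2 at 2.53 ± 0.10 and 4CL1 at 1.65 ± 0.08 of the phenylpropanoid pathway. CHS rose by 0.99 ± 0.33 at an adjusted p of 0.0353, which became 0.0562 with upper quartile factors, 0.0761 with no low-count filter, 0.0553 without UV-C replicate 1 and 0.122 without UV-C replicate 3. Abscisic acid and senescence genes rose in 8 of 15 cases and fell in 5 (camera adjusted p = 0.842), the senescence regulator ORE1 at 1.45 ± 0.13 and the cold- and drought-induced RD29A at -4.91 ± 0.28. Their median was 0.52 and their mean -0.07.

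All 14 measured clock genes changed after UV-C, 6 up and 8 down. The morning genes CCA1 and LHY rose by 4.93 ± 0.17 and 6.32 ± 0.23, and LNK2 by 3.06 ± 0.10, whereas the evening genes TOC1 (-1.46 ± 0.08), GI (-1.29 ± 0.14) and ELF3 (-1.54 ± 0.11) fell. As a list they did not pass camera (adjusted p = 0.597), and the median of -0.96 and the mean of 0.89 differed in sign. Of 6 known long non-coding RNAs 1 was called, ASCO (-0.92 ± 0.33, adjusted p = 0.0307), and none adjusted over the list alone (camera adjusted p = 0.764). The adjusted p of ASCO was 0.142 with DESeq2 and 0.0523 to 0.0983 without any of UV-C mock replicates 1, 2 and 3 or UV-C replicates 1 and 2. TAS1C had 0.38 ± 0.19 and passed, at 0.0332, without UV-C mock replicate 1. At the preset correlation 8 lists were called after UV-C, none was called with an estimated correlation, and other splits of the 6 libraries gave up to 10.

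**Figure D2:**
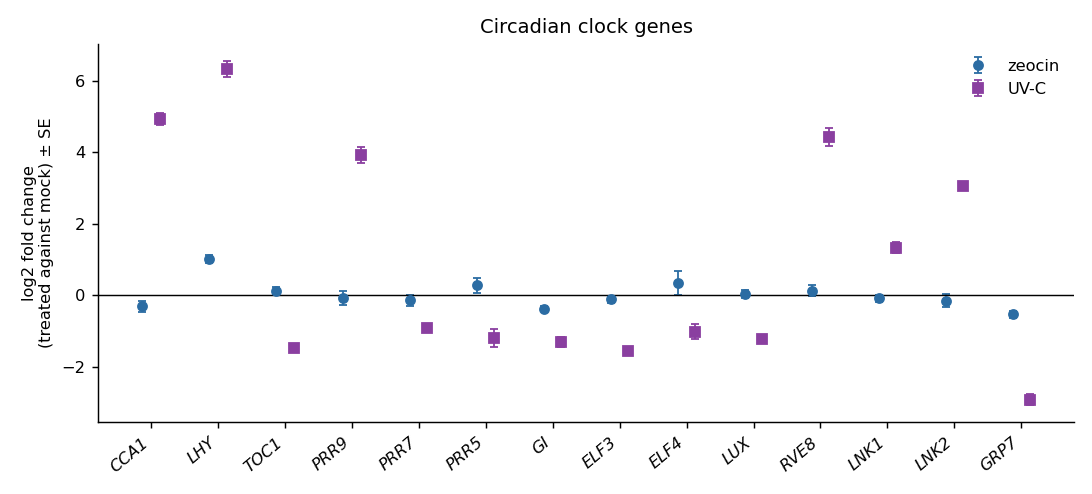
Log2 fold change of 14 circadian clock genes, treated against mock, after zeocin (circles, 5 against 5 libraries) and UV-C (squares, 3 against 3); bars are standard errors. LHY stands at 6.32 after UV-C and 1.02 after zeocin, and GRP7 at -2.91 and -0.53.

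Among the single-gene loci that rose strongly after UV-C were the non-coding AT5G00655 (chromosome 5, 21513800 to 21514399), with 1 count over the mock libraries and a ratio of 6403 (exact 95% interval 1149 to 252970), LCR67, a defensin-like gene, at 11.08 ± 0.30, the MATE transporter gene AT2G04070 at 10.97 ± 0.28, ABCG40 at 10.59 ± 0.16 and AT2G23270, with 3 mock counts and a ratio of 1715 (586 to 8320). Within the naming rule's limits the largest falls were AT5G62360 (-6.61 ± 0.40), AT1G07050 (-6.06 ± 0.29), AT5G23240 (-5.76 ± 0.16), AT3G62550 (-5.65 ± 0.24) and COR15B (-5.61 ± 0.40).

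**Figure D3:**
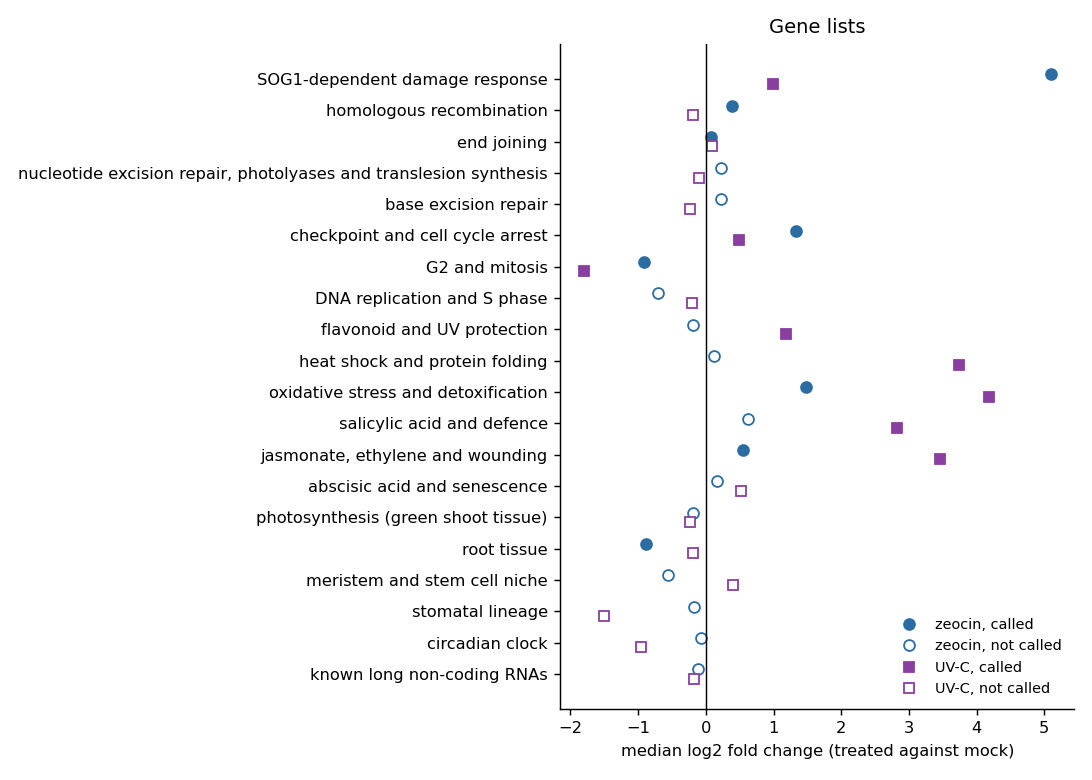
Median log2 fold change, treated against mock, of 20 gene lists after zeocin (circles) and UV-C (squares); filled symbols passed camera at an adjusted p below 0.05 with a preset correlation of 0.01. The SOG1-dependent list stands at 5.10 after zeocin and 0.99 after UV-C, and the heat shock list at 0.12 and 3.74.

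Whether a response differed between the treatments was tested by the interaction over 17305 matched loci. It called 4107 loci as higher after zeocin relative to UV-C, each against its own mock, and 4048 as lower. The dose and exposure differed between the experiments as well as the agent, and so did the assemblies and the mock groups. Whether the time of harvest differed is not known. Among the large positive differences were AT5G23910 (6.29 ± 0.22), the thymidine kinase gene TK1a (6.13 ± 0.20) and AT5G62360 (6.10 ± 0.65), which had fallen after UV-C. The differences of BRCA1 and CYCB1;1 were 5.80 ± 0.15 and 4.96 ± 0.18, that of SMR7 was 2.97 ± 0.62 on loci of unequal extent, and SOG1 did not pass (0.36 ± 0.22, adjusted p = 0.198) except without UV-C replicate 2 (adjusted p = 0.0188). Among the large negative ones were the dirigent gene DIR5 (-11.78 ± 0.91), the MATE genes AT2G04050 (-11.71 ± 1.95) and AT2G04070 (-10.92 ± 1.68), and AT2G44070 (-9.89 ± 1.29). The fitted sizes for DIR5 and AT2G44070 rest on 1 and 2 counts in the UV-C mock libraries. PHR1 did not pass (-0.67 ± 0.37, adjusted p = 0.147), and CHS did (-1.21 ± 0.33, adjusted p = 0.00779).

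Among the lists, SOG1-dependent genes were higher after zeocin relative to UV-C in 16 of 18 cases and lower in 1 (camera adjusted p = 1.22e-44), recombination genes in 17 and 1 of 25 (2.05e-16), checkpoint genes in 6 and 0 of 12 (0.00517), end joining genes in 4 and 0 of 9 (0.0119) and G2 and mitosis genes in 14 and 1 of 23 (0.000578). For G2 and mitosis this was a smaller fall after zeocin (median -0.92) than after UV-C (median -1.81), not a rise. Jasmonate genes were lower after zeocin in 10 and higher in 1 of 16 cases (5.94e-09), oxidative stress genes in 12 and 0 of 15 (8.10e-06), defence genes in 12 and 0 of 16 (5.02e-05), heat shock genes in 13 and 0 of 16 (7.69e-05) and flavonoid genes in 11 and 0 of 19 (8.70e-05). With an estimated correlation the calls of the SOG1-dependent (adjusted p = 7.96e-06), recombination (0.00224) and jasmonate lists (0.0280) held, and the others had adjusted p of 0.0992 for checkpoint, 0.244 for end joining and flavonoid, 0.348 for G2 and mitosis and 0.335 for oxidative stress, defence and heat shock. The other 10 lists had camera adjusted p of 0.0966 or more. In the replication, abscisic acid and clock lists the median and mean differed in sign (-0.52 and 0.08, -0.53 and 0.24, 0.89 and -0.84). Adjusted over the list alone, the counts were the same except for 1 rise in flavonoid genes, 13 falls in oxidative stress genes, 3 in place of 2 falls among meristem genes, and 2 rises and 1 fall in place of 3 and 2 among photosynthesis genes.

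Calls of the treatments overlapped in direction. Over 16321 matched loci tested in both, 1622 rose in both, where independent lists of these sizes share 801 (odds ratio 5.30, Fisher's exact adjusted p = 9.37e-299), and 1071 fell in both, where 677 would be shared (odds ratio 2.51, adjusted p = 1.29e-81). Opposite calls were fewer than independent lists give, 287 against 808 for rises after zeocin with falls after UV-C and 333 against 671 for the reverse. Loci are not independent replicates, so the p-values of these overlaps measure no spread between samples.

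The long non-coding RNAs of the design lie among the annotated non-coding and unannotated loci. Fisher's tests of locus classes, here and after UV-C, count loci that are not independent replicates, and their p-values measure no spread between samples. After zeocin 30 of 146 tested antisense loci rose and 7 fell, and 5 of 28 intergenic loci rose and 1 fell. Rises made up 81.1% of the antisense calls, against 54.8% of calls on protein-coding loci (Fisher's exact adjusted p = 0.00395). The difference did not pass among changes of at least 1 on the log2 scale (83.3%, adjusted p = 0.351). At that size 919 protein-coding loci rose and 384 fell, a higher rising share than among all their calls. The intergenic share of 83.3% rests on 6 calls (adjusted p = 0.289). Annotated non-coding loci rose in 24 and fell in 7 of 226 cases (77.4%, adjusted p = 0.0252, and 86.7% with adjusted p = 0.443 at a change of at least 1), and pseudogene and transposable element loci in 21 and 12 of 166 (63.6%, adjusted p = 0.381). Of the loci that hold several genes 126 rose and 58 fell (68.5%, adjusted p = 0.00151, and 83.9% with adjusted p = 0.351 at a change of at least 1). Among loci within the naming rule's limits on level and overlap, the largest rise was that of STRG.3739 of the zeocin assembly (chromosome 1, 22291520 to 22293860, minus strand, 1 exon), antisense to the dynamin-related gene DRP4C (AT1G60500), from 0.0644 ± 0.101 to 17.9 ± 1.91 CPM (SD, n = 5; log2 fold change 8.09 ± 0.42). It was followed by STRG.10955, antisense to AT3G27997 (4.37 ± 0.20), STRG.13757, antisense to AT4G15150 (2.35 ± 0.24), and STRG.1826, antisense to AT1G22230 (2.09 ± 0.15). STRG.4387, antisense to the cytokinin synthesis gene IPT1, fell (-1.11 ± 0.31). STRG.296, antisense to AT1G04540, had -0.62 ± 0.19 at an adjusted p of 0.0248, which became 0.0595 without zeocin mock replicate 1, 0.0501 without zeocin mock replicate 4 and 0.113 without replicate 1 of both groups.

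After UV-C 133 of 179 tested antisense loci rose and 19 fell, and 114 of 125 intergenic loci rose and 3 fell. Rises made up 87.5% of antisense calls (adjusted p = 5.52e-21) and 97.4% of intergenic calls (adjusted p = 8.12e-29), against 50.7% of calls on protein-coding loci. The residual rRNA and unannotated shares of the libraries rose with them. In 72 of the 125 intergenic and 38 of the 179 antisense loci every mock library had 0 counts. With these at their bound the median log2 fold changes were 4.64 and 4.48. Annotated non-coding loci rose in 112 and fell in 55 of 258 cases (67.1%, adjusted p = 6.86e-05), and pseudogene and transposable element loci in 47 and 34 of 139 (58.0%, adjusted p = 0.269). Rises also exceeded the protein-coding share among small structured RNAs (51 up and 15 down, 77.3%, adjusted p = 4.82e-05) and loci that overlap a gene in part (34 and 11, 75.6%, adjusted p = 0.00158). They did not among loci that hold several genes (161 and 158, 50.5%, adjusted p = 0.955), and plastid loci went the other way (1 and 10, 9.09%, adjusted p = 0.00900). STRG.20022 of the UV-C assembly (chromosome 5, 14889248 to 14889910, plus strand, 2 exons), antisense to the guard-cell potassium channel gene GORK (AT5G37500), had no mock counts and 37.0 ± 4.20 CPM after UV-C (SD, n = 3), at least 1349-fold higher over the group. STRG.17262, antisense to AT4G37380, rose with a ratio of 1155 (395 to 5603), and the intergenic STRG.21379 and STRG.7404 with ratios of 710 (196 to 5867) and 636 (217 to 3090). STRG.1254, antisense to AT1G13920, and STRG.19432, antisense to AT5G03615, fell (-3.84 ± 0.23 and -2.78 ± 0.39).

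**Figure D4:**
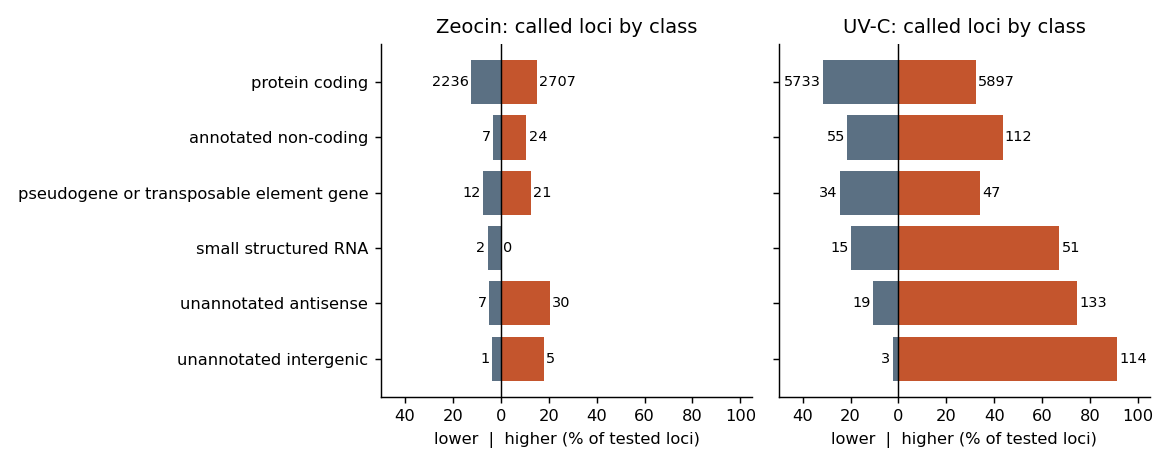
Percent of tested loci called as higher (right) or lower (left) after zeocin and UV-C, by class of locus; figures beside the bars are numbers of loci. After UV-C 114 intergenic loci rose and 3 fell.

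Of 103 unannotated loci matched between the assemblies 89 were tested, and 10 were higher and 17 lower after zeocin relative to UV-C. The 10 became 6 without any of UV-C mock replicates 1 and 3 or UV-C replicates 2 and 3. By their numbers in the zeocin assembly these included STRG.1116, antisense to AT1G13920 (4.94 ± 0.54), and STRG.3256 (2.36 ± 0.69) among the higher, and STRG.18779 (-3.80 ± 0.60) and STRG.3540 (-1.72 ± 0.36) among the lower. STRG.1088 (3.28 ± 1.16, adjusted p = 0.0311) did not pass with DESeq2 (0.115) or without any of zeocin mock replicate 4, zeocin replicates 1 and 4, UV-C mock replicates 1 and 3 and UV-C replicates 1 and 3 (0.0502 to 0.0709), and STRG.13757 (-2.24 ± 0.71, adjusted p = 0.0156) not without UV-C mock replicate 1 (0.0576) or 2 (0.0509). Of 43 matched loci tested in both experiments 6 rose in both, where 3.26 would be shared by independent lists (Fisher's exact p = 0.0549, adjusted p = 0.0878).

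Antisense loci and their sense genes were compared across loci, which are not independent replicates. After zeocin, over 30 pairs, Spearman's rho of the fold changes was 0.434 (permutation p = 0.0171, adjusted p = 0.0258) and Pearson's r 0.513 (permutation p = 0.00650, adjusted p = 0.0130), or 0.479 without the 2 outermost pairs. The relation depended on which locus stood for a sense gene held by several: with the first in the table rho was 0.292 (permutation p = 0.118, adjusted p = 0.118) and r 0.356 (permutation p = 0.0479, adjusted p = 0.0479), or 0.462 without the 2 outermost, so that only r passed. After UV-C, over 29 pairs, rho was 0.414 (permutation p = 0.0258, adjusted p = 0.0258) and r 0.389 (permutation p = 0.0361, adjusted p = 0.0361), or 0.417 without the 2 outermost. With the first locus the adjusted p of rho was 0.0545 and that of r 0.0479. Antisense loci exceeded their sense genes by a median of 3.92 on the log2 scale after UV-C. Loci of the opposite strand overlapped only 23 of the 257 antisense loci in the zeocin table and 5 of the 348 in the UV-C table. In the 29 UV-C pairs the sense gene was therefore mostly counted over another part of its length. For the 30 zeocin pairs the overlap was not counted.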

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

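Tests of the clock genes against scaling, of the unannotated loci against scaling and read-through, of antisense loci whose sense gene is measured, and of mature transcript length were chosen after the results were seen.

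Of 134 groups of 5 values 7 held a library whose gap to its neighbour passed Dixon's critical ratio of 0.71, and chance gives about 1 in 20. In zeocin mock replicate 2 AT2G28780 stood at 30.97 CPM against 24.4 to 25.9 in the others and SMR7 at 0.6953 against 0.230 to 0.354. AT1G20750 stood at 0.2009 CPM in zeocin mock replicate 1, where the others reached 0.0236, HAI1 at 1.5 CPM in zeocin mock replicate 5 against 0.545 to 0.758, and TAS1A at 7.414 CPM in zeocin mock replicate 3 against 6.22 to 6.35. LIG4 stood at 50.82 CPM in zeocin replicate 2 against 44.0 to 44.9. Residual rRNA took 0.006034% of counts in zeocin mock replicate 4 and at most 0.000551% in the others. No biological explanation of these values was tested.

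After UV-C all 14 clock genes changed, 6 up and 8 down. The morning genes CCA1 and LHY rose, and the evening genes TOC1, GI and ELF3 fell. The choice of library scaling is argued against: the smallest absolute change of a clock gene was 0.9163 (log2), and the largest shift between scalings was 0.107. Collection of the treated seedlings at another time of day predicts that clock-controlled genes outside the list follow their phase. On average they did, and 11 of 14 dawn genes rose and 4 of 5 dusk genes fell past the threshold: the dawn genes had a mean log2 fold change of 2.06 ± 1.71 (SD) and the dusk genes -1.55 ± 1.29, a difference of 3.607 (exact permutation p = 0.000344 over 11628 arrangements, two-sided). The permutation counts genes, which are not independent replicates, so its p measures no spread between samples. A shift of the clock by UV-C itself could give the same values. The labels give no harvest times, so a time-of-day difference stays open for these and other rhythmic genes.

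Most unannotated loci called after UV-C rose. The share of rises was at least 91.11% with RLE factors, with upper quartile factors and with organellar and rRNA loci removed. This argues against the choice among these scalings as the source. All of them take counts relative to the library, so a change in the total amount of RNA was not examined. Of 114 rising intergenic loci 23 (20.18%, exact 95% interval 13.2% to 28.7%) began within 1000 bases of the end of a gene on their strand, which argues against read-through of up to that length as the main source, and longer read-through was not tested. Wrong-strand reads of the opposite gene were to be tested against the counts of overlapping loci; 0% of 133 rising antisense loci met the criterion, but 130 had no opposite-strand counts to compare with, so this decides nothing. In 23 of the 25 rising antisense loci whose sense gene was measured, the antisense change exceeded the sense change. The median excess was 4.395 (95% bootstrap interval 2.14 to 5.27), with fitted changes not set to a bound where mock counts were 0. The sense genes were mostly counted over another part of their length. The excess therefore argues against a fixed share of wrong-strand reads only if the sense change was alike along the gene, which was not tested. The 25 loci were chosen because they rose, so some excess is built in. The smallest differences were -0.82 (STRG.15450), -0.77 (STRG.4479), 0.31 (STRG.10593) and 0.60 (STRG.7475). For these loci, and for those without a measured sense gene, wrong-strand reads and a biological source cannot be told apart. For the other measured loci this holds unless the sense change was alike along the gene.

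Log2 fold changes after UV-C fell with gene span (Spearman's rho -0.123 over 18224 genes, medians 0.28 in the shortest and -0.12 in the longest decile). Within 5 bins of exonic length the mean rho was -0.09892 (-0.132 to -0.0443), and within 5 bins of exonic GC content -0.1157 (-0.142 to -0.0808). The trend thus remained within bins of either. Both properties still vary within a bin, so the bins do not settle whether either accounts for the whole trend. A biological explanation, such as lesions that block transcription more often in long genes, may apply and was not tested further.

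Chance as the source of the calls was examined by refitting other splits of the samples. For zeocin 1 of 100 splits, the real one, gave as many loci (5245, the highest other 1) or unannotated loci (43, the highest other 0), a share below 0.05. Every other split mixed treated and mock libraries within a group, which widens the spread within groups and lowers the calls. The splits say nothing of single loci or of a batch. As many lists (8, the highest other 13) came from 41 of 100 splits, so chance is not excluded for that number. For UV-C the 10 splits are too few for a share under 0.05: 12623 loci against at most 0, 269 unannotated loci against at most 0 and 8 lists against at most 10, the real split included in 1, 1 and 6 splits as large. For the difference 18 of 100 splits gave 10 lists or more (highest other 12), so chance is not excluded for that number. For loci 2 of 100 splits gave 8155 or more (highest other 8656), and for unannotated loci 7 gave 27 or more (highest other 38). Neither decides anything, because both counts follow the UV-C labels. The 11 other splits that kept these labels called at least 6114 loci and at least 18 unannotated loci. The 87 that parted neither experiment as labelled called 0 of both. Among the 12 that kept the UV-C labels, the real one included, 2 were as large for loci and 7 for unannotated loci.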

How the results depend on the processing

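The fits without replicate 1 of both zeocin groups and with the first locus of a sense gene were added after the data were seen. Total counts of calls stayed within 1.5 times the values reported under DESeq2, RLE and upper quartile factors, a filter of at least 10 counts, removal of organellar and rRNA loci, 80% overlap and each left-out library. A threshold of 1 on the log2 change left 1410 loci for zeocin, 5541 for UV-C and 3966 for the difference, by construction. With no low-count filter unannotated calls were 73 for zeocin and 612 for UV-C, since more loci were tested. With an estimated correlation camera called 3, 0 and 3 lists for zeocin, UV-C and the difference in place of 8, 8 and 10, and fry, which does not compare a list with other genes, called 15 for zeocin and 14 for UV-C. At a change of at least 1 the rising shares after zeocin were 86.6667% for annotated non-coding (adjusted p = 0.443), 83.3333% for antisense (0.351) and 68.4211% for pseudogene and transposable element loci, which came to lie below protein-coding loci (adjusted p = 0.804). The antisense relation after zeocin had rho 0.485714 over the 6 pairs with both loci at a mean log2 CPM of at least 1 (exact permutation p = 0.356) and 0.291657 with the first locus; after UV-C only 2 pairs were left and no value was computed. PHR1 (zeocin), never called, turned to 0.0993087 without zeocin mock replicate 3 and 0.0577673 without zeocin replicate 5, in a range from -0.201257 to 0.0993087 over the left-out libraries. The cause was not tested where none is given.

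With each library left out in turn, calls ranged from 4202 to 5520 for zeocin (unannotated 38 to 51, with 5 in place of 8 falls without any of zeocin mock replicates 1 and 4 or zeocin replicates 3 and 4), from 11647 to 12125 for UV-C (277 to 318) and from 7233 to 8699 for the difference (21 to 28, with 6 in place of 10 higher loci without any of UV-C mock replicates 1 and 3 or UV-C replicates 2 and 3). Without replicate 1 of both groups zeocin gave 5447 calls, 4680 of them shared, and 5 unannotated falls. Correlations of same-numbered libraries ran from -0.0957 to 0.435 for zeocin and from -0.300 to 0.155 for UV-C, so replicate numbers do not pair the samples throughout. For zeocin the highest of all mock and treated pairs were those of replicate 1 (0.435) and replicate 3 (0.254). A batch shared by some numbers is therefore not excluded, and the labels do not say whether the numbers mark one. With the replicate block the counts were 5675, 12128 and 8086, camera also called the salicylic acid list after zeocin (adjusted p = 0.000786), and ASCO lost its call. In simulations with 200 changed loci per draw, a change of 0.5 was recovered in 26.4% of loci for zeocin, 32.8% for UV-C and 6.40% for the difference. Far more loci were called in the data, and recovery at that number of changes was not measured.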

Other observations

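The following genes, known from meiosis or gametes, were chosen after their values in zeocin-treated seedlings were seen, and no list of such genes was tested. MND1 and AHP2 (AT1G13330), which act together in strand exchange and were on the recombination list, rose from 1.03 ± 0.263 to 33.4 ± 2.59 CPM and from 0.974 ± 0.156 to 25.9 ± 1.87 CPM (SD, n = 5), with log2 fold changes of 5.01 ± 0.15 and 4.73 ± 0.12 (edgeR adjusted p = 3.27e-12 and 5.72e-13). GEX1, known from gametes and embryos, rose from 0.361 ± 0.184 to 124 ± 19.7 CPM (8.43 ± 0.23, adjusted p = 8.99e-12). The meiotic recombinase gene DMC1 had a log2 fold change of 0.27 ± 0.13 and did not pass (adjusted p = 0.151).

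After UV-C 1 short locus took a large share of the libraries. STRG.1401 of the UV-C assembly (chromosome 1, 5297825 to 5298163), which holds the genes AT1G05163 and AT1G15405, took 1.57% ± 0.0941 of counts in mock and 5.60% ± 0.826 in UV-C libraries (SD, n = 3; edgeR log2 fold change 2.04 ± 0.14, adjusted p = 1.12e-06). It was also chosen after its values were seen.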
